A study of Mus musculus with 15 samples.

How the data were processed

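Bulk RNA sequencing of liver from 8-week-old male C57BL/6J mice was measured 1 day after 1 intraperitoneal injection of saline, cisplatin or doxorubicin, with 5 mice per group and 1 library per mouse, as the sample labels give them. The labels state 10 mg/kg for both drugs. Cisplatin was given at 1 mg/mL in saline and doxorubicin at 2 mg/mL in sterile water, so that vehicle and injected volume differed between the drugs. The sequenced RNA was selected by its poly(A) tail. The design note of the series says that the samples lack information on doxorubicin, whereas the sample labels name it and its dose; the sample labels were followed. The last doxorubicin column of the table bears another number than the last doxorubicin label. It was matched as the remaining library of its group and is called the unnumbered doxorubicin library.

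Per the submitters' processing notes, the authors trimmed reads with Trim Galore 0.4.1, aligned them with HISAT2 2.0.1 to GRCm38 (mm10), counted them with featureCounts 1.4.6 and used edgeR, for which no version is given. The deposited table holds FPKM, fragments scaled to gene length and to library size, for 21878 genes in 15 columns, and 0 columns were left unused. The annotation release and strand setting behind the table are not stated. For low genes the FPKM values moved in steps of 1 read, and the values of all 17788 genes above 0 in at least 1 library were whole multiples of such a step within 0.0001 of a read. The gene length was searched up to 130000 bases for a fit. For a gene above 0 in only 1 library some length nearly always fits, so the match is no test there. Library totals were recovered from these steps and the exon lengths of genes in the reference annotation; 143 genes gave the same totals, and the next most frequent total was given by 12. The recovered totals were 27.6 to 34.7 M reads (megareads) in the saline libraries, 25.3 to 31.0 M in the cisplatin libraries and 37.6 to 50.7 M in the doxorubicin libraries. The reads recovered over all genes made up 99.999 to 100% of each total. These totals, called depth below, thus count reads assigned to genes, and the number of reads sequenced is not known. In a gene of 1 kb, 1 read was 0.0396 FPKM in the shallowest library and 0.0197 in the deepest. The reference annotation behind these totals was GENCODE release M21. Genes were placed on GRCm38 with the RefSeq gene table, which matched 20458 symbols directly and 882 through older symbols, while 538 were not placed.

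The FPKM values were used as deposited, without further scaling. Genes with at least 1 FPKM in at least 5 of the 15 libraries were tested, which left 10552. The values were transformed to log2(FPKM + 1), which shrinks the changes of genes with low values. A single limma 3.58.1 fit in R 4.3.3 with the 3 groups as its only term (eBayes with trend and robust settings) gave the 3 comparisons, each two-sided and with Benjamini-Hochberg adjustment over all tested genes at 0.05. All fold changes are differences of mean log2(FPKM + 1), with the standard error of the fit. Gdf15, Ern1 and Xbp1 were also compared with exact two-sided permutation tests of 5 against 5 libraries, whose smallest possible p is 0.00794. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

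The tests, the alternatives and 43 gene lists (27 of pathways and 16 of cell type markers), written from general knowledge, were fixed before the data were examined. Lists with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01, which compares the members with all other genes, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry, a test of whether the members move on balance one way, were the alternatives. For each list, changed members were counted after adjustment over all genes and adjusted over the list alone. Several genes stand in more than 1 list. The rule for named genes was also fixed beforehand: Gdf15, Ern1 and Xbp1; in each comparison the 10 largest rises and 10 largest falls among changed genes whose groups did not overlap, without unnamed gene models and pseudogenes; and in each list at most 3 changed members per direction with the smallest adjusted p. Not all of these genes are named in the text, and some results are not reported here. The choice among them was made after their values were seen and favored genes whose calls held under the alternatives. Reads of near-identical genes (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, and members of the Cyp2 families) cannot be assigned with certainty.

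Alternatives were pseudocounts of 0.1 and 0.5, no filter and a stricter filter (mean FPKM of at least 5), rescaling to TPM, median-ratio scaling, quantile normalization, a fit of only the 2 groups compared, the replicate number as a block, eBayes without trend and robust settings, each library left out in turn, a minimum absolute log2 change of 1 and an adjusted p of 0.01. After the data were seen, voom on the recovered reads, reads thinned to 25255949 per library, and a fit without saline 2 and the unnumbered doxorubicin library were added. The overlap of both drug responses was set beside 100 simulated unchanged data sets and 20 splits of the saline libraries between the comparisons. Other groupings were tested with 100 of the 126 possible splits of 10 libraries. The procedure was tested on simulated data with 200 planted changes per drug comparison and 8 false calls in each. In both, 59 of 67 planted 2-fold changes were recovered, and 36 and 37 of 67 planted 1.5-fold changes in the cisplatin and doxorubicin comparisons. The simulated genes varied independently of each other, and fewer were changed than were called in the real data. These rates need not hold where genes vary together between libraries. Mitochondrially encoded genes were absent from the table, and that list could not be counted. No library was left out of the main comparisons.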

Results

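The data were poly(A)-selected RNA sequencing profiles of mouse liver 1 day after an injection of saline, cisplatin (a platinum compound that crosslinks DNA) or doxorubicin (an anthracycline that poisons topoisomerase II). Each group held 5 libraries, which the labels give as separate mice, and the deposited FPKM values were compared on the log2(FPKM + 1) scale in 10552 genes. The mean depth, in reads assigned to genes, was 29.84 ± 2.869 M reads (megareads) in the saline group, 28.64 ± 2.338 M in the cisplatin group and 44.46 ± 6.107 M in the doxorubicin group (SD, n = 5 each). The doxorubicin libraries (37.6 to 50.7 M) did not overlap the others (25.3 to 34.7 M). The labels give no sequencing run, so a separate run of the doxorubicin libraries would be confounded with the drug in each comparison that includes them. Saline 2 stood apart from its group, with 73% of genes above or below all other saline libraries where 40% would be so by chance. Cisplatin was given in saline and doxorubicin in sterile water, at different volumes, so doxorubicin differs in vehicle from both other groups. The labels do not give the saline volume, the food intake of the mice or the hour of sampling, and effects of these cannot be separated from those of the drugs. The series title names hepatic IRE1α (gene Ern1), a sensor of protein folding in the endoplasmic reticulum, and GDF15, a circulating protein that lowers food intake.

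Gdf15, the gene of this hormone (chromosome 8, 70629393 to 70632470, GRCm38), was higher after both drugs. Its level was 9.57 ± 2.69 FPKM after saline, 40.1 ± 14.2 after cisplatin and 47.5 ± 11.1 after doxorubicin (mean ± SD, n = 5 each), which made the drug means 4.19 and 4.96 times the saline mean. On the log2 scale it rose by 1.95 ± 0.23 (SE, limma adjusted p = 5e-05) after cisplatin and by 2.22 ± 0.23 (adjusted p = 2.96e-06) after doxorubicin. The exact permutation p was 0.00794 for each drug, the smallest that 5 against 5 libraries can give. The difference between the drugs was 0.27 ± 0.23 (adjusted p = 0.463), which did not exceed the spread. The lowest saline value, 4.92 FPKM in saline 3, lay apart from the other saline values.

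Xbp1 (chromosome 11, 5520641 to 5525993), whose mRNA is spliced by IRE1α into the code of an active transcription factor, was 72.6 ± 2.11 FPKM after saline, 95.4 ± 17.3 after cisplatin and 142 ± 8.85 after doxorubicin (SD, n = 5 each). It rose by 0.96 ± 0.10 on the log2 scale after doxorubicin (adjusted p = 2.86e-06), and doxorubicin exceeded cisplatin by 0.59 ± 0.10 (adjusted p = 0.000587). After cisplatin it rose by 0.37 ± 0.10 (adjusted p = 0.0232), a call that ended without saline 5 (adjusted p = 0.0522) or cisplatin 1 (0.0571), with only the 2 groups in the fit (0.0508) and with replicate numbers as a block (0.0601). Ern1 (chromosome 11, 106397620 to 106487796) was 8.90 ± 1.82, 7.82 ± 1.29 and 8.25 ± 2.85 FPKM in the saline, cisplatin and doxorubicin groups, and its differences of -0.16 and -0.14 from saline were within the spread (adjusted p = 0.66 and 0.625). The table gives 1 value per gene and cannot separate spliced from unspliced Xbp1 mRNA.

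**Figure D1:**
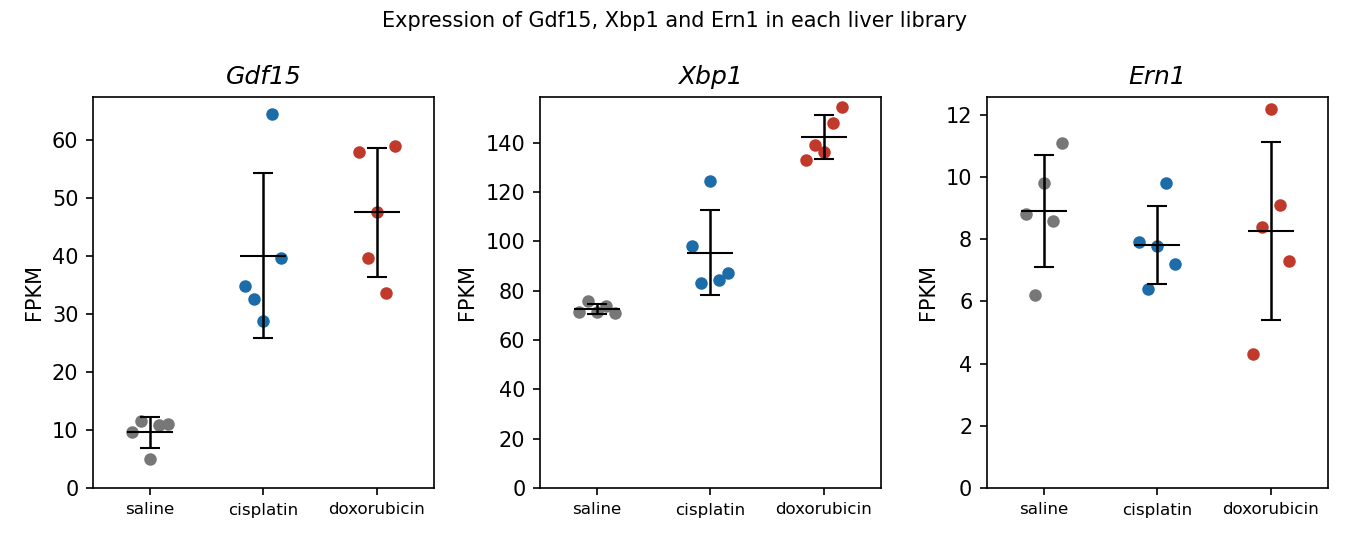
Expression of Gdf15, Xbp1 and Ern1 (FPKM, linear axes from 0) in each liver library. Points are libraries, and bars are the group mean ± SD (n = 5). All drug values of Gdf15, from 28.8 to 64.5 FPKM, lie above the highest saline value of 11.5.

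After cisplatin compared with saline, targets of the DNA damage regulator p53 and enzymes of cholesterol synthesis were higher, and hemoglobin transcripts were lower. Of 10552 tested genes, 642 rose and 528 fell, and 72 and 62 of these by at least 2-fold; with no filter on low values 580 rose and 610 fell. Phlda3, a p53-induced inhibitor of AKT signaling (chromosome 1, 135766085 to 135769134), went from 0.397 ± 0.106 to 13.5 ± 5.95 FPKM (SD, n = 5 each), and Sqle, the squalene epoxidase of cholesterol synthesis (chromosome 15, 59315092 to 59331193), from 8.87 ± 3.81 to 41.9 ± 12.3. Hba-a1, an adult alpha globin gene (chromosome 11, 32283672 to 32284486), went from 201 ± 52.2 to 10.3 ± 3.73 FPKM.

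Among 28 tested p53 targets, 18 rose and 0 fell, and the counts adjusted over the list alone were also 18 and 0. Phlda3 rose by 3.28 (adjusted p = 2.11e-07), Ccng1, a cyclin G induced by p53, by 1.94 (3.88e-06) and Aen, an apoptosis-associated nuclease, by 1.61 (1.27e-05). The list was higher relative to other genes by camera (adjusted p = 1.59e-15), with adjusted p = 0.122 with an estimated correlation.

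Protein folding genes of the endoplasmic reticulum were also higher. In the IRE1-XBP1 list, 12 of 24 members rose, 14 when adjusted over the list alone, and 0 fell (camera adjusted p = 5.55e-09, adjusted p = 0.306 with an estimated correlation). Sdf2l1, a chaperone cofactor, rose by 1.70 ± 0.25 (adjusted p = 0.000374), and the disulfide isomerase Pdia6 and the cochaperone Dnajb11 by 0.97 and 0.79. In the ATF6 list, 8 of 12 rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 1.19e-07, adjusted p = 0.306 with an estimated correlation). The calcium-binding chaperone Calr rose by 1.21 ± 0.11 (adjusted p = 3.15e-06), from 266 ± 14.1 to 624 ± 101.5 FPKM (SD, n = 5). Herpud1, a component of endoplasmic reticulum-associated degradation, fell by 0.57 (adjusted p = 0.0443). Its call ended in most of the fits with 1 library left out, for example without saline 3 (adjusted p = 0.105). It also ended with no filter (0.0731), median-ratio scaling (0.0683), only the 2 groups in the fit (0.0828) and the replicate block (0.0958). Among 6 tested substrates of IRE1-dependent decay, the lysosomal enzyme gene Hgsnat rose by 0.36 (adjusted p = 0.00686) and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.056). Of 21 targets of the integrated stress response, Sesn2 rose by 0.57 (adjusted p = 0.0216) and 0 fell, again with the same counts adjusted over the list alone (camera adjusted p = 0.631).

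All 25 cholesterol synthesis genes were measured. Of these, 24 rose and 0 fell, and 25 rose when adjusted over the list alone (camera adjusted p = 1.07e-26, adjusted p = 0.122 with an estimated correlation). Their median change was 1.28. Idi1, Sqle, Fdps, Mvd and Cyp51, enzymes along the route from mevalonate to sterols, rose by 2.26, 2.17, 2.08, 2.05 and 1.97. Fdft1, the squalene synthase, rose from 18.6 ± 4.29 to 70.5 ± 16.6 FPKM (SD, n = 5 each). Outside the list, Apoa4, an apolipoprotein of triglyceride-rich particles, rose from 153 ± 18.1 to 903 ± 296 FPKM (SD, n = 5 each; adjusted p = 4.01e-06). Fatty acid synthesis genes went both ways, with 6 of 19 higher and 1 lower over all genes and adjusted over the list alone (camera adjusted p = 0.0238, adjusted p = 0.506 with an estimated correlation). That list call ended without saline 2 (adjusted p = 0.15), cisplatin 1 (0.0729) or cisplatin 2 (0.0849) and with quantile normalization (0.0616). Srebf1, a transcription factor of lipid synthesis, rose by 0.99 (adjusted p = 0.00966).

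PPARα targets and fatty acid oxidation genes were lower, with 0 of 25 rising and 6 falling, or 8 falling adjusted over the list alone (camera adjusted p = 0.00401, adjusted p = 0.568 with an estimated correlation). Angptl4, a secreted inhibitor of lipoprotein lipase, fell by 1.37 (adjusted p = 0.000494) and the peroxisomal thiolase Acaa1b fell by 1.07 (0.00893). Of 24 genes of gluconeogenesis and amino acid catabolism, 0 rose and 3 fell, or 8 adjusted over the list alone (camera adjusted p = 0.0131, adjusted p = 0.411 with an estimated correlation). This list call ended without saline 4 (adjusted p = 0.0594). Prodh, the proline dehydrogenase, fell by 0.66 (adjusted p = 0.00728). Among 19 bile acid genes, 1 rose and 2 fell, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.0203, adjusted p = 0.122 with an estimated correlation). Cyp27a1, the sterol 27-hydroxylase, fell by 0.64 (adjusted p = 9.15e-05), and Akr1d1, a bile acid reductase, rose by 0.53 (0.0131).

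Acute-phase genes, which code for plasma proteins made by the liver in inflammation, were higher in part. Of 25, 7 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000635, adjusted p = 0.394 with an estimated correlation), and the list call ended without saline 2 and the unnumbered doxorubicin library (adjusted p = 0.0505). Serpina3n rose by 1.51 (adjusted p = 0.00195) and Apcs, serum amyloid P, by 1.17 (7.49e-05). Lcn2, an iron-siderophore binding protein, rose by 2.76 ± 0.61 (adjusted p = 0.0097), with 940 FPKM in cisplatin 2 and 54.9 to 220 in the other cisplatin libraries. Among 21 cytokine and NF-kB genes, 1 rose and 1 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.486); the neutrophil attractant Cxcl1 rose by 1.29 (adjusted p = 0.000293). Among 27 interferon-stimulated genes, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.631), with a median of -0.01 and a mean of 0.03, and the nucleic acid sensor Zbp1 rose by 1.05 (adjusted p = 0.000332).

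Among cell type markers, 5 of 7 erythroid genes fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 1.68e-07, adjusted p = 0.122 with an estimated correlation). Hba-a1 fell by 4.20 ± 0.40 and Hbb-bt fell by 3.84 ± 0.39 (SE, adjusted p = 9.18e-06 and 1.37e-05). Of 14 markers of sinusoidal endothelial cells, 0 rose and 4 fell, or 5 adjusted over the list alone (camera adjusted p = 0.000188, adjusted p = 0.394 with an estimated correlation). Stab2, a scavenger receptor of these cells, fell from 7.45 ± 1.67 to 2.95 ± 0.669 FPKM (SD, n = 5 each; adjusted p = 0.000119). Among changed genes, the largest fall outside the globins was in Immp2l, a mitochondrial peptidase subunit spanning 932 kb of chromosome 12 (41024061 to 41955588), from 26.9 ± 2.98 to 2.54 ± 0.86 FPKM (adjusted p = 6e-09). Wwox, an oxidoreductase gene spanning 913 kb of chromosome 8, fell from 3.98 ± 0.414 to 0.481 ± 0.123 FPKM (adjusted p = 2.11e-07).

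The values of cisplatin and saline livers did not overlap in 1025 genes, 9.7% of those tested, where chance gives 0.79%. Without cisplatin 3 the number of changed genes was 720 in place of 1170. With an estimated correlation camera called 0 of 35 lists (5 at an unadjusted p under 0.05), and fry called 12, with 10 of the 17 main calls among them.

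After doxorubicin compared with saline, genes of the interferon response, the acute phase and protein folding were higher, together with markers of monocytes and neutrophils, while bile acid and amino acid metabolism genes were lower. In total 1520 genes rose and 1815 fell, with 235 and 173 of these changing at least 2-fold. Which direction held more genes depended on the scaling, as 1808 rose and 1658 fell with median-ratio scaling and 1385 rose and 2008 fell on the TPM scale. Cxcl1 (chromosome 5, 90891245 to 90893121) went from 5.65 ± 1.17 to 180 ± 24.1 FPKM (SD, n = 5 each), Derl3, a component of endoplasmic reticulum-associated degradation (chromosome 10, 75893398 to 75895941), from 1.73 ± 1.29 to 66.1 ± 44.4, and Cyp8b1, the sterol 12α-hydroxylase of cholic acid synthesis (chromosome 9, 121914356 to 121916305), from 297 ± 43.9 to 65.8 ± 45.

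Of the 28 p53 targets, 20 rose and 1 fell, or 20 and 2 adjusted over the list alone (camera adjusted p = 3.93e-13, adjusted p = 0.126 with an estimated correlation). Phlda3 rose by 3.82 (adjusted p = 1.15e-08), Ccng1 by 2.17 (2.59e-07) and Eda2r, a receptor of the tumor necrosis factor family, by 1.60 (5.12e-07). The stress-induced gene Sesn1 fell by 0.28 (adjusted p = 0.0192), a call that ended without saline 2 and the unnumbered doxorubicin library and with replicate numbers as a block.

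In the IRE1-XBP1 list, 22 of 24 members rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.49e-15, adjusted p = 0.129 with an estimated correlation). Sdf2l1 rose by 3.08 ± 0.25 (adjusted p = 2.96e-07), Pdia6 by 1.67 and Dnajb11 by 1.61. Of 12 ATF6 targets, 11 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 9.72e-12, adjusted p = 0.126 with an estimated correlation). Derl3 rose by 4.46 ± 0.49 (adjusted p = 1.03e-05), Creld2 by 2.80, the secreted folding factor Manf by 2.49 and Calr by 1.68. The integrated stress response list was split, with 7 of 21 higher and 3 lower over all genes and adjusted over the list alone (camera adjusted p = 0.324); its median change was 0.11 and its mean -0.02. The tRNA synthetase genes Wars, Nars and Cars rose by 1.14, 0.55 and 0.52. Trib3, a pseudokinase induced in amino acid stress, fell from 7.19 ± 0.792 to 1.42 ± 0.298 FPKM (SD, n = 5 each; adjusted p = 2.52e-07), and the asparagine synthetase gene Asns fell by 0.65 (adjusted p = 0.00342). Among the 6 IRE1-dependent decay substrates, 0 changed, also adjusted over the list alone (camera adjusted p = 0.4).

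All 27 interferon-stimulated genes rose, also adjusted over the list alone, with a median change of 0.98 (camera adjusted p = 1.48e-22, adjusted p = 0.0626 with an estimated correlation). Zbp1 went from 5.52 ± 0.904 to 44.5 ± 6.83 FPKM (SD, n = 5 each), Xaf1 rose by 1.65 and Irf7, the transcription factor that amplifies the interferon response, by 1.64. Of 25 acute-phase genes, 21 rose and 0 fell, or 22 and 0 adjusted over the list alone (camera adjusted p = 1e-16, adjusted p = 0.0626 with an estimated correlation). Lcn2 rose by 3.68 ± 0.61 (adjusted p = 0.000364), the acid glycoprotein gene Orm2 by 3.12, Apcs by 2.18 and Lrg1 by 1.98. Of 21 cytokine and NF-kB genes, 8 rose and 1 fell, or 10 and 1 adjusted over the list alone (camera adjusted p = 8.22e-05, adjusted p = 0.182 with an estimated correlation). Cxcl1 rose by 4.78 ± 0.18 (adjusted p = 5.5e-11), and the monocyte attractant Ccl7 by 1.70 (3.13e-08). Sod2, the mitochondrial superoxide dismutase, fell by 0.39 (adjusted p = 0.00236).

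Markers of neutrophils and monocytes were higher in the same libraries. Of 14 listed neutrophil markers only 3 passed the filter and were tested. All 3 rose, also adjusted over the list alone: S100a9 by 2.30 (adjusted p = 1.7e-06), S100a8 by 2.05 and the receptor Csf3r by 1.14. The filter of 5 libraries can be met by 1 group alone, so a marker may have been tested because it was high after doxorubicin. This limit also applies to the monocyte markers, of which 8 of 14 were tested. Of 8 monocyte and infiltrating macrophage markers, 6 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 3.02e-05), and this call held with an estimated correlation (adjusted p = 0.0159). Ly6c2 rose by 1.65, Plac8 by 1.12 and Ms4a6c by 1.09. Among 12 markers of Kupffer cells, the resident macrophages, 7 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0165, adjusted p = 0.498 with an estimated correlation). The list call ended without saline 2 (adjusted p = 0.058) or doxorubicin 2 (0.0777). The scavenger receptor gene Marco went from 2.35 ± 1.15 to 21.5 ± 4.73 FPKM (SD, n = 5 each), the complement gene C1qa rose by 0.88, and the iron exporter Slc40a1 fell by 0.91 (adjusted p = 4.65e-05). Of 14 sinusoidal endothelial markers, 1 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.0163, adjusted p = 0.521 with an estimated correlation). Stab2 fell by 0.77, and the hyaluronan receptor Lyve1 rose by 0.86 (adjusted p = 0.0106). Of 7 erythroid genes, 5 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.000857, adjusted p = 0.182 with an estimated correlation), and Hba-a1 fell by 2.51 ± 0.40 (adjusted p = 0.000217). Of 7 B cell markers, 0 rose and 5 fell, or 6 adjusted over the list alone (camera adjusted p = 0.0137, adjusted p = 0.269 with an estimated correlation).

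Genes of bile acid and amino acid metabolism were lower. Of 19 genes of bile acid synthesis and transport, 0 rose and 12 fell, or 15 adjusted over the list alone (camera adjusted p = 2.9e-05), and the call held with an estimated correlation (adjusted p = 0.0129). Cyp8b1 fell by 2.63 ± 0.55 (adjusted p = 0.00208), the bile acid importer Slc10a1 fell by 1.24 and the conjugating enzyme Baat fell by 0.66. Of 24 genes of gluconeogenesis and amino acid catabolism, 17 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 1.37e-06, adjusted p = 0.146 with an estimated correlation). Oat, the ornithine aminotransferase, went from 730 ± 159 to 199.5 ± 33.5 FPKM (SD, n = 5 each; adjusted p = 2.96e-07), and the aspartate aminotransferase Got1 fell by 1.87. Of 25 PPARα targets, 0 rose and 11 fell, or 13 adjusted over the list alone (camera adjusted p = 6.3e-05, adjusted p = 0.471 with an estimated correlation), and Acot1, an acyl-CoA thioesterase, fell by 1.91. Among 21 xenobiotic cytochromes P450 and their regulators, 4 rose and 10 fell, or 6 and 12 adjusted over the list alone (camera adjusted p = 0.0163, adjusted p = 0.182 with an estimated correlation). Cyp2c37 fell by 1.74 and Cyp2e1 fell by 1.35, while Cyp3a13 rose by 0.99. Cholesterol synthesis genes rose in 7 of 25 cases and fell in 0, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.532 with an estimated correlation), and the list call ended without saline 2 (adjusted p = 0.0912). Sqle rose by 1.44 (adjusted p = 0.000577). Fatty acid synthesis genes included 1 that rose and 5 that fell of 19, also adjusted over the list alone (camera adjusted p = 0.0749); Srebf1 rose by 1.03 and the elongase Elovl5 fell by 1.57.

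The values of doxorubicin and saline livers did not overlap in 2317 genes, 22% of those tested, where chance gives 0.79%. Only the bile acid and the monocyte list calls held with an estimated correlation. With replicate numbers as a block the number of changed genes was 2170 in place of 3335.

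**Figure D2:**
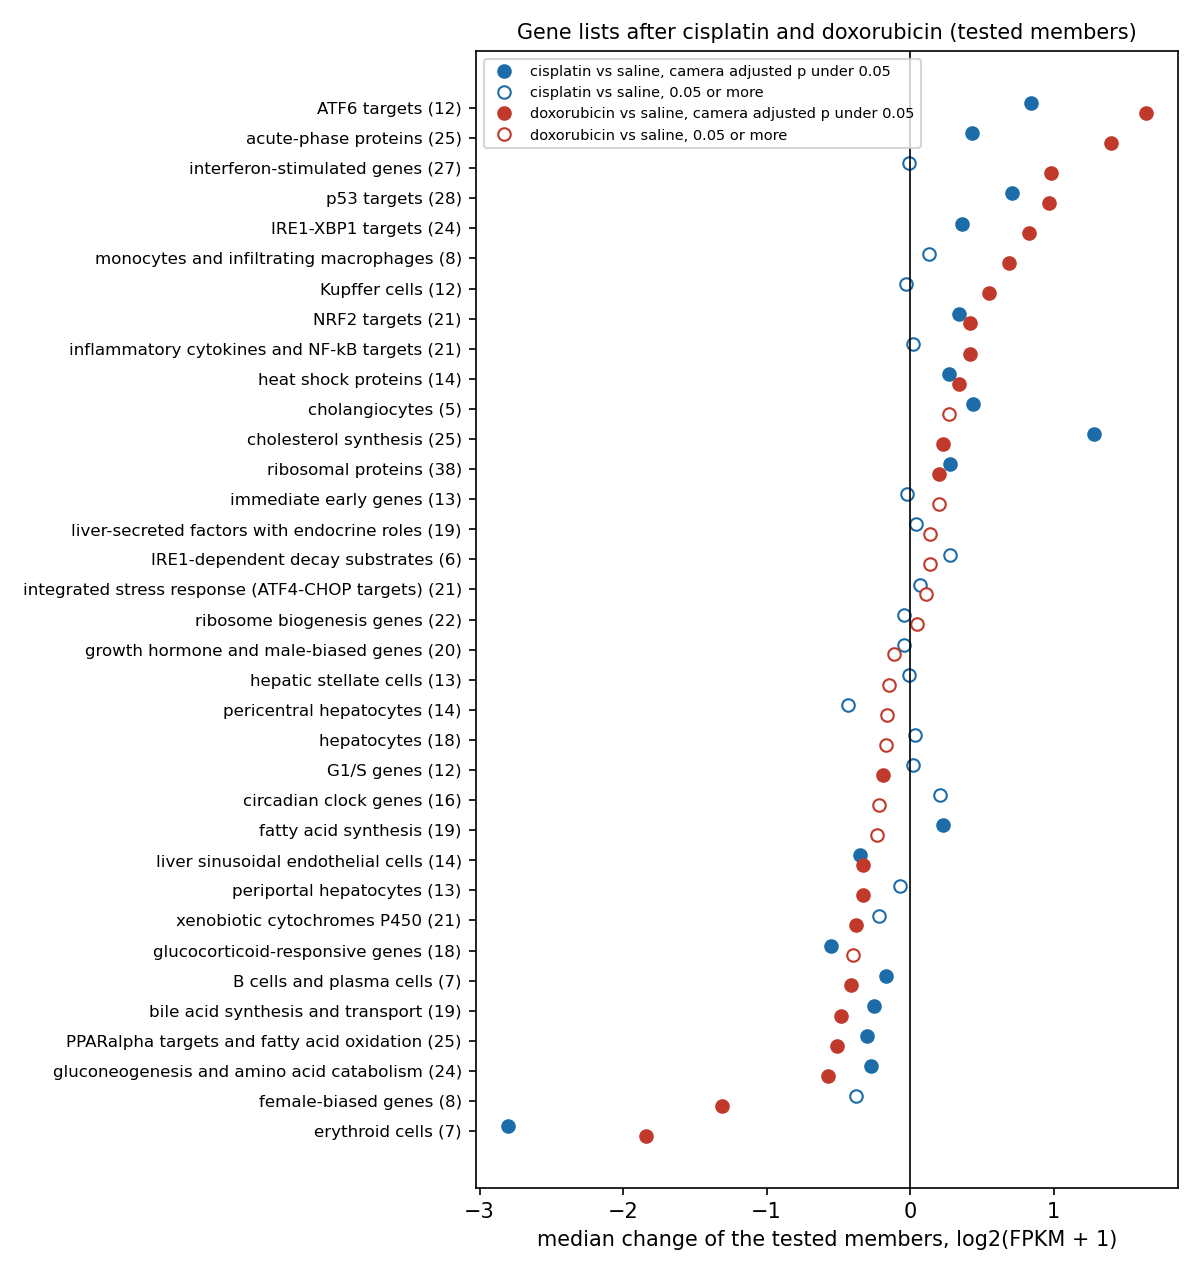
Median change of the tested members of each gene list, in log2(FPKM + 1), after cisplatin (blue) and doxorubicin (red) compared with saline. Numbers in brackets are tested members, and filled points have a camera adjusted p under 0.05 at the preset correlation. Cholesterol synthesis lies at 1.28 after cisplatin, and ATF6 targets lie at 1.64 after doxorubicin.

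Doxorubicin was compared directly with cisplatin at the same dose per body weight. Interferon-stimulated, acute-phase and protein folding genes were higher after doxorubicin, and cholesterol synthesis and circadian clock genes were lower. In all, 950 genes were higher after doxorubicin and 1201 lower, with 135 and 87 of these differing at least 2-fold. This balance depended on the processing, as 1189 were higher and 1125 lower with no filter, and 1124 higher and 1132 lower with median-ratio scaling. Dnajc12, a cochaperone of aromatic amino acid hydroxylases, differed by 3.22 ± 0.12 (SE, adjusted p = 9.68e-11). Bhmt, the betaine-homocysteine methyltransferase (chromosome 13, 93616891 to 93637758), was 3158 ± 360 FPKM after cisplatin and 814 ± 255 after doxorubicin (SD, n = 5 each; adjusted p = 1.17e-06).

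Of 27 interferon-stimulated genes, 26 were higher after doxorubicin and 0 lower, also adjusted over the list alone (camera adjusted p = 5.11e-29), and the call held with an estimated correlation (adjusted p = 0.0496). Zbp1 differed by 1.75 and Irf7 by 1.47. Of 25 acute-phase genes, 17 were higher and 0 lower, or 19 and 0 adjusted over the list alone (camera adjusted p = 1.97e-14, adjusted p = 0.0966 with an estimated correlation). Of 21 cytokine and NF-kB genes, 8 were higher and 1 lower, or 11 and 1 adjusted over the list alone (camera adjusted p = 5.69e-06, adjusted p = 0.196 with an estimated correlation); Cxcl1 differed by 3.49 ± 0.18 (adjusted p = 8.14e-09). In the ATF6 list, 11 of 12 were higher, also adjusted over the list alone (camera adjusted p = 6.98e-08, adjusted p = 0.235 with an estimated correlation), with Derl3 differing by 2.68. In the IRE1-XBP1 list, 15 of 24 were higher and 0 lower, or 19 and 1 adjusted over the list alone (camera adjusted p = 1.24e-08, adjusted p = 0.268 with an estimated correlation), with Sdf2l1 differing by 1.38. Of 28 p53 targets, 6 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.0036, adjusted p = 0.546 with an estimated correlation). Monocyte markers were higher in 4 of 8 cases and lower in 0, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.000117), and the call held with an estimated correlation (adjusted p = 0.0496).

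Of 25 cholesterol synthesis genes, 20 were lower after doxorubicin than after cisplatin and 0 higher, or 22 and 0 adjusted over the list alone (camera adjusted p = 1.05e-12, adjusted p = 0.235 with an estimated correlation). Hmgcs1, the HMG-CoA synthase, was 226 ± 70 FPKM after cisplatin and 66.6 ± 15.9 after doxorubicin (SD, n = 5 each; adjusted p = 4.8e-05), and Cyp51 differed by -1.80. Of 19 bile acid genes, 6 were lower and 0 higher, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.0036), and the call held with an estimated correlation (adjusted p = 0.0496). Slc10a1 differed by -0.95 (adjusted p = 0.000178). Of 24 genes of gluconeogenesis and amino acid catabolism, 10 were lower and 0 higher, or 12 and 1 adjusted over the list alone (camera adjusted p = 3.76e-05, adjusted p = 0.235 with an estimated correlation), with Got1 differing by -1.80. In the clock list, 8 of 16 were lower and 1 higher, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00528, adjusted p = 0.304 with an estimated correlation). Dbp, a clock output transcription factor, was 43.2 ± 24.3 FPKM after cisplatin and 4.37 ± 1.08 after doxorubicin (SD, n = 5 each; adjusted p = 0.0015), against 8.52 ± 6.87 after saline. Immp2l was higher after doxorubicin than after cisplatin by 2.22 ± 0.15 (adjusted p = 1.09e-07). Values of both drugs did not overlap in 1725 genes, 16.3% of those tested, where chance gives 0.79%, and with replicate numbers as a block the number of differing genes was 1260 in place of 2151.

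The responses to both drugs shared 797 changed genes. Of these, 396 rose after both drugs, 376 fell after both and 25 changed in opposite directions, where independent lists of the same sizes would share 92.5 and 90.8 genes in the same direction. Phlda3, Ccng1 and Sdf2l1 were among those that rose after both drugs. The responses use the same saline libraries, which adds to the overlap. In 100 simulated data sets with unchanged groups that shared their saline libraries, the median number of same-sign genes was 0 (range 0 to 2). Almost no gene passes the threshold where no group is changed. This number therefore cannot show how much the shared libraries added to the observed overlap. With the saline libraries split between the comparisons, the median of 20 splits was 337.5 same-sign genes (range 190 to 658), with 684.5 and 2480.5 changed genes for cisplatin and doxorubicin. The split medians were 177.5 genes higher and 160.5 lower after both drugs. Independent lists of the split sizes would share medians of 32.3 and 34.1. At the median, the overlap thus exceeded that of independent lists also without shared saline libraries. Across genes, which are not independent replicates, the Pearson correlation of both log2 changes was 0.609, which lay within the range of the simulated unchanged data (0.0587 to 0.815, median 0.515), and the median of the split saline libraries was 0.475. The covariance was 0.0871, against a simulated median of 0.0104 (range 0.00146 to 0.038) and 0.0742 with split saline libraries.

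**Figure D3:**
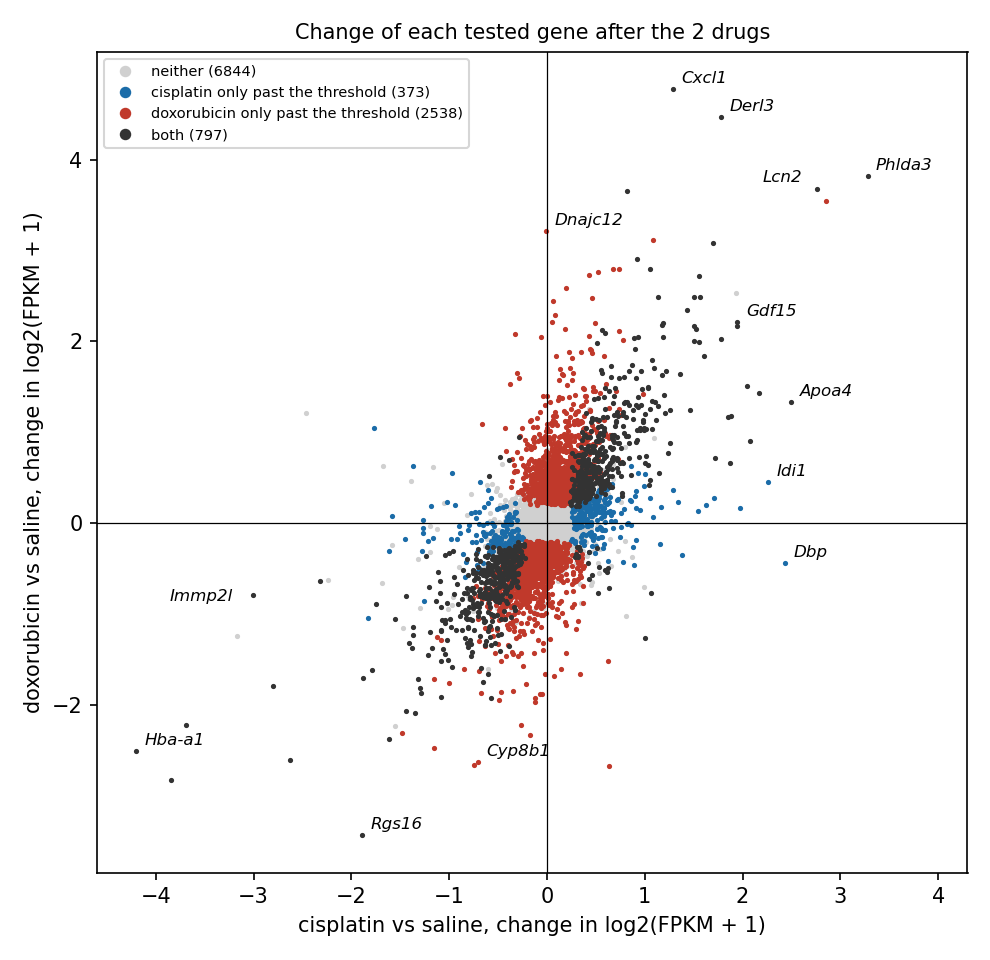
Change in log2(FPKM + 1) after cisplatin (horizontal axis) and doxorubicin (vertical axis) compared with saline, 1 point per tested gene. Black points passed the threshold for both drugs (797 genes), blue for cisplatin alone (373), red for doxorubicin alone (2538) and grey for neither (6844); passing for 1 drug alone does not show a difference between the drugs. Gdf15 lies at 1.95 and 2.22.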

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

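The tests on hemoglobin reads and on the share of hepatocytes were chosen only after the results were seen. Among 93 groups of 5 values examined, 8 (8.6%) held a value far from the other 4, where chance gives about 1 in 20. In saline 3, Gdf15 was 4.924 FPKM (9.615 to 11.52 in the other saline libraries) and Bhmt 3168 FPKM (2241 to 2450). In cisplatin 2, Lcn2 was 939.6 FPKM (54.92 to 219.7), and in cisplatin 3, Derl3 was 22.31 FPKM (4.005 to 7.402). In doxorubicin 1, Ccng1 was 93.86 FPKM (54.68 to 63.8), and in doxorubicin 2, Dbp was 2.506 FPKM (4.512 to 5.243). The sum of FPKM of the unnumbered doxorubicin library was 592500 (548100 to 555400). The 10 most abundant genes took 16.1% of the reads of saline 2 (18.29 to 19.09% in the other saline libraries). The cisplatin call of Derl3 (adjusted p = 0.0311) ended without cisplatin 3 (adjusted p = 0.0649), but also without saline 2 (0.0788), saline 3 (0.0724), saline 4 (0.0646) or cisplatin 1 (0.0575), with voom (0.0878) and without saline 2 and the unnumbered doxorubicin library (0.077). The call was thus fragile, and these fits do not show how much of it rested on cisplatin 3.

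Hemoglobin transcripts fell after both drugs, to 6.11% of the saline level after cisplatin (2.72 to 8.09% in single libraries) and 23.4% after doxorubicin (7.28 to 60.4%) for the 4 adult genes together. This sum does not depend on how reads were shared between the near-identical genes, which argues against that assignment as the cause. Less blood in the pieces of liver would lower all blood cell transcripts alike, provided that they came from blood alone. Platelet markers were at 67.1% and lymphocyte markers at 74.2% of saline after cisplatin, and both differed from hemoglobin (exact permutation p = 0.00794 each). After doxorubicin they were at 74.2 and 76.1% (exact permutation p = 0.0238 and 0.0159 against hemoglobin). The fall of hemoglobin was thus not matched by these markers, but cells of the liver tissue may also carry them, which was not tested. The part that a lower blood content played therefore cannot be sized. A smaller number of young red cells, which still hold mRNA, remains a hypothesis that was not tested.

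Macrophage, monocyte and neutrophil markers rose after doxorubicin, with a median of 23 markers that was 0.636 above saline (exact permutation p = 0.00794). Only markers past the filter were included, and high values after doxorubicin alone could meet it. A lower share of hepatocytes would raise the markers of all other cell types, but the median of 27 stellate and sinusoidal endothelial markers differed by -0.193 (exact permutation p = 0.135), and the difference between both sets was 0.829 (exact permutation p = 0.00794). The 5 cholangiocyte markers went the other way and were 0.241 above saline (exact permutation p = 0.00794), which was 0.395 less than the immune markers (exact permutation p = 0.0476). With these included, the median of 32 markers differed by -0.168 (exact permutation p = 0.19), and the immune markers lay 0.804 above it (exact permutation p = 0.00794). Of the 14 sinusoidal endothelial markers alone, 1 rose and 6 fell, which could hide a rise from composition. Of the 13 stellate markers, 0 rose and 1 fell, with a median change of -0.15. A lower share of hepatocytes as the whole cause is thus argued against. Thinning all libraries to equal reads, because the doxorubicin libraries held more reads assigned to genes, left the median difference at 0.636. Since thinning keeps the expected FPKM of each gene, it could hardly alter this median and does not decide whether depth played a part. A separate sequencing run was not testable. These data cannot tell more immune cells in the tissue from higher expression in the cells present, so an influx of cells may be proposed only as a hypothesis.

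Chance division of the libraries was tested with 100 of the 126 splits of each 10 libraries, the real one included. It was unlikely in all 3 comparisons, but so few splits cannot exclude it. The other splits mix libraries of both groups, which widens the spread on each side, so their counts do not measure false calls. For cisplatin against saline only 1 split, the real one with 1170 changed genes, gave as many, and the highest other gave 121. For doxorubicin against saline it was also 1, with 3335 changed genes and 389 in the highest other, and for doxorubicin against cisplatin 1, with 2151 and 56.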

How the results depend on the processing

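The fits with voom, with thinned reads and without saline 2 and the unnumbered doxorubicin library were chosen after the data were seen. No called gene named in the text and no called list changed its direction in any alternative, but the balance of rises and falls did. For doxorubicin against saline, 1520 rose and 1815 fell in the main fit, 1808 rose and 1658 fell with median-ratio scaling and 1385 rose and 2008 fell on the TPM scale. With no filter, 580 rose and 610 fell for cisplatin against saline in place of 642 and 528, and 1189 were higher and 1125 lower between the drugs in place of 950 and 1201, where median-ratio scaling gave 1124 and 1132. Gdf15 stayed past the threshold for both drugs in every alternative, and leaving out 1 library gave log2 changes of 1.75 to 2.05 after cisplatin, 2.02 to 2.33 after doxorubicin and 0.17 to 0.45 between the drugs. Counts of changed genes with 1 library left out ran from 720 (without cisplatin 3) to 1241 for cisplatin against saline, from 2795 to 3461 for doxorubicin against saline and from 1734 to 2706 between the drugs; the cause of the low value without cisplatin 3 was not tested. With the replicate block the counts were 2170 for doxorubicin against saline and 1260 between the drugs, and 792 for cisplatin. The labels do not say whether a shared number pairs mice. No pairing was seen, as 0 of 14 numbered libraries correlated best with a library of their own number. The median correlation was -0.014 for pairs with the same number and 0.015 for other pairs, which does not exclude a pairing. The block costs degrees of freedom. It also takes the unnumbered doxorubicin library, which has no partner, out of the estimates; without that library and with no block the counts were 3088 and 1892, and the cause of the further loss was not tested. A minimum absolute log2 change of 1 gave 134, 408 and 222 genes and an adjusted p of 0.01 gave 482, 2034 and 1160, by construction of stricter thresholds. Voom gave 1103, 3422 and 2201, thinned reads 1123, 3269 and 2119, and the fit without the pair of libraries 1303, 3230 and 2554, of which 978, 2797 and 2007 were among the genes of the full fit. All other counts stayed within 1.5 times of the main value.

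With an estimated correlation 0, 2 and 3 lists were called in place of 17, 22 and 17, and with fry 12, 25 and 18, with 10, 21 and 15 of the main calls among them; an estimated correlation widens the test where members vary together between libraries. Leaving out 1 library gave 14 to 21, 20 to 23 and 16 to 20 lists. Among 56 list calls, 10 ended with fry. After cisplatin these were acute-phase proteins (adjusted p = 0.0539), PPARα targets (0.159), fatty acid synthesis (0.146), gluconeogenesis and amino acid catabolism (0.0591), glucocorticoid-responsive genes (0.0844), heat shock proteins (0.138) and sinusoidal endothelial cells (0.0539). After doxorubicin it was cholesterol synthesis (0.143), and between the drugs p53 targets (0.0965) and PPARα targets (0.206). Apart from an estimated correlation and fry, 12 ended in at least 1 alternative, and 16 with fry included; among the 12 were heat shock proteins after cisplatin (adjusted p = 0.0699 without cisplatin 3), B cells after cisplatin (0.144 without saline 4, 0.104 without cisplatin 4), periportal hepatocytes after doxorubicin (0.0648 without saline 1) and PPARα targets between the drugs (0.17 without the unnumbered doxorubicin library). Of 193 calls of the genes named in the text, 173 held in every alternative in which the gene was tested. When 1 library was left out, 13 of the 193 ended. The stricter filter covered 162 of these calls, and the stricter thresholds on log2 change and adjusted p were applied only to counts. The choice of named genes favored calls that held, so these shares do not describe all changed genes. With the saline libraries split between the comparisons, the same-sign overlap was 337.5 genes in place of 772, with fewer controls per comparison. At the depth of the shallowest library, 1 read of a 1 kb gene is 0.0396 FPKM. Genes that reached 1 FPKM in fewer than 5 libraries were not tested. Simulated changes of 1.5-fold were recovered in 53.7 and 55.2% of cases, with genes that varied independently.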

Other observations

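Other gene lists changed as well. Of 21 NRF2 targets, 7 rose after cisplatin and 12 after doxorubicin and 0 fell, or 8 and 12 adjusted over the list alone (camera adjusted p = 1.46e-05 and 2.9e-05, adjusted p = 0.306 and 0.234 with an estimated correlation); the epoxide hydrolase Ephx1 rose by 1.07 and 1.34, and the glutathione transferase Gsta1 rose by 2.59 after doxorubicin. All 38 ribosomal protein genes had positive changes after cisplatin, of which 16 rose, or 24 adjusted over the list alone (camera adjusted p = 5.88e-13, adjusted p = 0.301 with an estimated correlation), and 13 rose after doxorubicin, also adjusted over the list alone (camera adjusted p = 4.94e-05, adjusted p = 0.471 with an estimated correlation). Of 18 glucocorticoid-responsive genes, 1 rose and 5 fell after each drug, or 1 and 6 adjusted over the list alone; only the cisplatin list was called (camera adjusted p = 0.00401, adjusted p = 0.394 with an estimated correlation; doxorubicin 0.157), and the difference between the drugs had an adjusted p of 0.442. The gene that rose was Lcn2, which also belongs to the acute-phase list, and the feedback regulator Errfi1 fell by 0.68 after cisplatin and fell by 0.78 after doxorubicin. In the clock list, 4 of 16 rose and 1 fell after cisplatin, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.14), with Dbp at 2.44 and Per3 at 1.54. After doxorubicin 0 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.23). The labels give no hour of sampling.

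Female-biased genes were lower after doxorubicin. Of 8 tested female-biased genes, 0 rose and 4 fell, or 5 adjusted over the list alone (camera adjusted p = 0.00761, adjusted p = 0.268 with an estimated correlation); Acot3 fell by 2.32 and Cyp17a1 fell by 1.87. Of 20 growth hormone and male-biased genes, 0 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.322), and Socs2, a feedback inhibitor of growth hormone signaling, fell by 1.63 (adjusted p = 0.0037). Of 12 G1/S genes, 0 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0344, adjusted p = 0.268 with an estimated correlation), a list call that ended without saline 1 (adjusted p = 0.0608), saline 4 (0.0679) or the unnumbered doxorubicin library (0.0623) and with no filter (0.0818); Tk1 fell by 1.32 and Rrm2 fell by 1.29. Among 14 heat shock genes, 5 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00458, adjusted p = 0.471 with an estimated correlation), and Hsp90aa1 rose by 1.25. Among 19 liver-secreted factors, 7 rose and 4 fell, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.413). Hepatocyte markers rose in 2 and fell in 5 of 18 cases, also adjusted over the list alone (camera adjusted p = 0.156), and the liver regulators Hnf4a and Cebpa fell by 0.49 and fell by 0.41. Stellate cell markers fell in 1 of 13 cases, or 0 adjusted over the list alone (camera adjusted p = 0.829).

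Genes with long gene bodies fell after cisplatin, a pattern noticed in Immp2l and Wwox, and the threshold of 300 kb was chosen only after the result was seen. These 2 genes were left out of all counts and tests of the pattern. Of 136 other genes spanning 300 kb or more, 71 (52.2%) fell and 3 rose, against 98 (3.8%) that fell among 2613 genes under 10 kb; after doxorubicin the shares that fell were 37.5% and 12.7%. The median of 1073 genes of 100 kb or more, less that of the other genes, differed by -0.108 between cisplatin and saline (exact permutation p = 0.00794, adjusted p = 0.0119). Once each library's trend on exon length, GC content and expression was removed, the difference was -0.064 (exact permutation p = 0.0476, adjusted p = 0.0714), so such a bias may account for a part of it, whereas at 300 kb or more it was -0.31 of -0.372 (exact permutation p = 0.00794), which argues against that bias as the whole cause. After doxorubicin the difference was -0.11 at 100 kb or more (exact permutation p = 0.00794), or -0.054 once the trends were removed (exact permutation p = 0.0476, adjusted p = 0.0714), and -0.208 at 300 kb or more, or -0.144 (exact permutation p = 0.00794 each). Between the drugs it was -0.002 at 100 kb or more (exact permutation p = 0.929) and 0.164 at 300 kb or more (exact permutation p = 0.00794), so that a difference between the drugs was seen only at the threshold chosen afterwards. Adam11, which fell by 2.32 after cisplatin, spans 19 kb and lies outside the pattern. Reduced transcription across long gene bodies predicts these differences, but so does any other cause of less mRNA from long genes, and that explanation was left open.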
